A study of Homo sapiens with 17 samples.

How the data were processed

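RNA-seq was analysed in 9 libraries, 3 each of NC, 2-DG and Nala, with groups and replicate numbers taken from the library names in the labels. The deposited table holds RPKM, reads scaled by gene model length and by the counted total of the library, for 17808 genes, with 1 column per library. Per the submitters' processing notes the genome build was hg38 and the tools named for the 3 assays together were HISAT2 2.1.0, Bowtie2 2.2.5, RSEM 1.2.8, DESeq, fastp 0.23.1, STAR 2.7.6a, MACS2 2.2.7.1 and HOMER 4.8.3. Which of these the authors used for the RPKM values, whether repeated reads were removed and whether strand was used are not given in the sources used here. The labels name a BGI mRNA library kit.

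Values of a gene were whole multiples of the value of 1 read for 100% of genes, within 0.0001 reads, for gene models up to 150000 bp. This gave the counted total of each library, from 6199778 to 6653130 reads, and the recovered reads made up 99.9% of each total. A read in a 1 kb gene is worth 0.150 to 0.161 RPKM, which sets the step of low values. Depth differed little between libraries.

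Replicate pairs were compared on the recovered reads by a chi-square test over genes with a mean of at least 10 reads. Nala replicates 2 and 3 agree within sampling noise and were averaged into 1 sample, so that 8 samples entered the fit, 3, 3 and 2 per group, with 5 residual degrees of freedom. The averaging was decided after the data were examined but before its effect on the calls was seen. The design fixed beforehand counted 3 libraries of Nala, and that fit is among the alternatives.

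Genes with at least 1 RPKM in at least 3 of the 9 libraries were tested, 12922 in all. Values were taken as log2(RPKM + 1), and the 3 groups were fitted together with limma 3.58.1 (R 4.3.3), with an intensity trend in the prior variance. The p-values were adjusted by Benjamini-Hochberg within a comparison and genes with an adjusted p under 0.05 were called. No covariate was used. RPKM values are not counts, so no count model was the main test and DESeq2 was not used. The median log2 fold change of all genes stayed within 0.1 of 0 under each scaling tried.

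Before the data were examined 38 gene lists were fixed from textbook knowledge of glucose deprivation, lactate, liver cells and other cell types. The 34 lists with at least 5 tested genes were tested with camera at a preset correlation of 0.01, adjusted over lists within a comparison. Camera with an estimated correlation and fry were alternatives. None of the lists called in the 3 comparisons (15, 8 and 14) was called with an estimated correlation. With fry, which tests whether the genes of a list move on balance one way and does not compare a list with other genes, 12, 1 and 12 of them were called. Camera with an estimated correlation also tests with the 5 residual degrees of freedom alone, so few lists could pass. Mitosis, with all 33 genes lower with 2-DG, had an unadjusted camera p of 0.0163 in that form. The estimated correlation was under the preset 0.01 for the hyperosmotic (-0.036), mesenchymal (-0.0058) and WNT (0.0030) lists. For these 3 lists a higher correlation does not account for the lost call.

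The genes named were chosen by a rule fixed beforehand. It took the 6 genes with the largest rise and the 6 with the largest fall among called genes with at least 10 RPKM in the higher group and groups that do not overlap, leaving out clone and pseudogene symbols. It added the 3 called members with the largest change in each of the 6 lists with the smallest camera p, and 10 genes followed in every comparison. For genes changed in opposite directions it took up to 5 in each pattern. Other genes named as examples of a list or as part of a small count were picked after their values were seen.

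Comparisons against the same NC libraries share their chance values, so overlaps and the correlation are set beside 50 simulations of unchanged groups. These simulations hold no changed genes, so they give no chance level for groups in which many genes changed. Gene positions come from the RefSeq annotation of GRCh38.p14, the assembly of the hg38 build, and 17697 symbols matched it directly and 86 through an older symbol. Alternatives were another pseudocount of 0.1, no filter, a filter of 5 RPKM, 3 scalings, no trend and a fit of the compared groups alone. A minimum fold of 2, the replicate number as a block and each library left out were others. The fit with the pair of Nala libraries kept apart was planned as the main fit and became an alternative when the pair was averaged. The block was run with the pair apart, a form chosen after seeing the data, as was voom on the recovered reads.

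The fits were tested on simulated data with 200 changed genes. For 2-DG against NC the share of changed genes recovered was 16% at a fold of 1.25, 78% at 1.5, 96% at 2 and 100% at 4, and 7.05% of the calls were of unchanged genes. For Nala against NC, with 2 samples, the shares were 14%, 68%, 96% and 98%, and 4.17% of the calls were of unchanged genes. Of 100 random lists, 4 and 1 had a camera p under 0.05. The simulated genes varied independently of each other with 1 dispersion (0.00296), and changed genes were drawn above a minimum of reads. The estimated correlation was 0.408 for the mitosis list and 0.510 for ribosomal proteins. The random lists therefore do not show how camera at a preset 0.01 behaves for lists of correlated genes. Python 3.11.15, numpy 2.4.6 and pandas 2.3.3 read the table. The ChIP-seq and ATAC-seq samples, with 1 library each, were not analysed here.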

Results

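The series covered 17 samples from cells given as HepG2, a human liver cancer line, and addressed the response of these cells to metabolic stress, with BRD9 and histone lactylation named in its title. The values analysed here were RNA-seq levels in 9 libraries, 3 each of untreated cells (NC), cells given 40 mM 2-DG and cells given 40 mM Nala. 2-DG is 2-deoxyglucose, a glucose analogue that enters glycolysis but is not metabolised through it. Nala is given here as the labels write it. The 6 ChIP-seq and 2 ATAC-seq samples were not analysed here. Sample titles gave 24 h for NC and 48 h for 2-DG, so that time in culture was not separated from treatment. For Nala the titles gave 48 h and the series design 24 h. Each library held between 6199778 and 6653130 counted reads over 17808 genes, of which 12922 passed the filter on low values. The highest value in the table was 229.6 RPKM.

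Several transcripts typical of hepatocytes were close to 0 in the untreated cells as well as the treated ones. APOB, the structural protein of liver lipoproteins, lay between 0 and 0.011 RPKM over the 9 libraries (0 to 1 read). Of the 29 listed hepatocyte secreted proteins 14 were in the table, and of the 36 genes held from that list and the one of liver regulators, 22 had a mean under 1 RPKM in every group. CEBPA lay between 14.01 and 33.9 RPKM and VTN, which encodes vitronectin, between 9.94 and 69.2 RPKM. SMARCB1, a core subunit of the SWI/SNF chromatin remodeller, lay between 0 and 1.59 RPKM, with 18 reads in NC replicate 2 and 0 in NC replicates 1 and 3. Some genes used by most cells were low too, with the aldolase ALDOA between 3.31 and 5.23 RPKM and the fatty acid synthesis enzyme ACACA between 0.143 and 0.635 RPKM, while GAPDH lay between 124.8 and 151.7 RPKM. KRT7, a keratin of ductal epithelia, lay between 110.0 and 140.3 RPKM and the adhesion molecule L1CAM between 117.2 and 143.1 RPKM. SMARCB1, ALDOA, ACACA, GAPDH, KRT7 and L1CAM were singled out after their values were seen.

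Over all genes compared, replicates 2 and 3 of Nala differed by less than the sampling noise, and they were counted as 1 sample. Their chi-square per degree of freedom was 0.904 over 12887 genes (chi-square p = 1), while replicate 1 of Nala gave 3.05 and 2.78 against them and the pairs within NC and 2-DG gave 2.09 to 9.84. Over the 3222 genes with the fewest reads per base the pair differed slightly beyond that noise, at 1.05 (chi-square p = 0.0229). Over as many of the densest genes the value was 0.746. The series design states 3 biological replicates, and the values of the pair were not identical. Means, SDs and tests for Nala are over n = 2, ranges over libraries cover all 3 of them, and the number of genes called with the pair kept apart is given beside that of each comparison. The SD for Nala is that between replicate 1 and the mean of replicates 2 and 3. It can be far smaller than the spread of the 3 libraries.

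**Figure D1:**
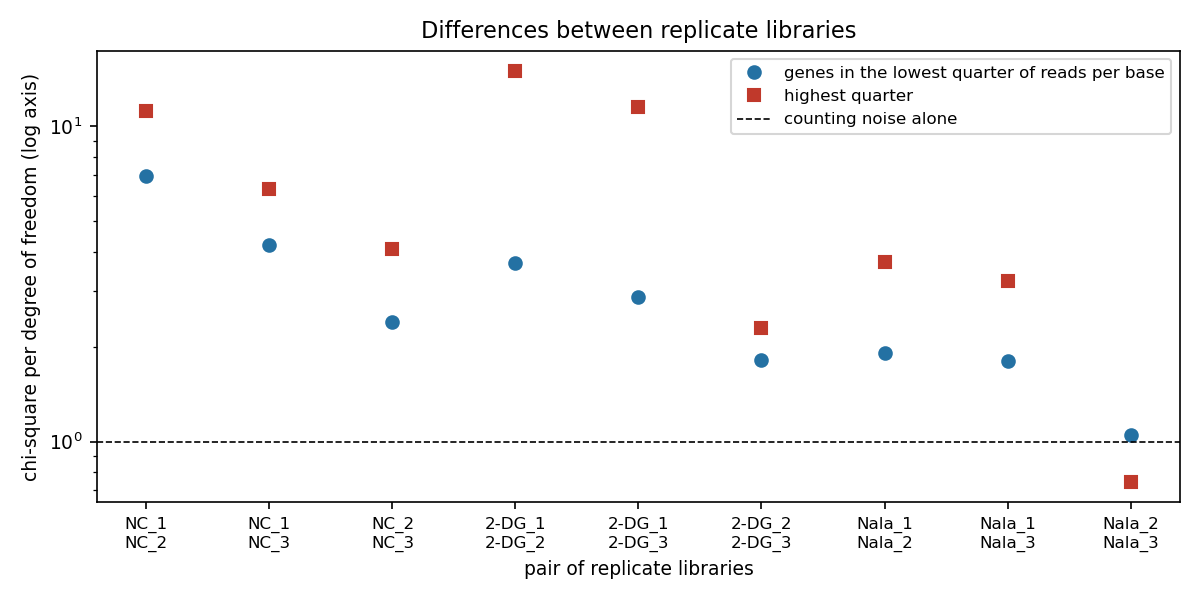
Chi-square per degree of freedom (log axis) for each pair of replicate libraries, over the genes with the fewest reads per base (circles) and over those with the most (squares), with the value of counting noise alone as a dashed line. The pair of Nala replicates 2 and 3 lies at 1.05 and 0.746, while each of the other pairs lies above the line.

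With 2-DG, genes of cell division fell together and most tested genes of the p53, amino acid and endoplasmic reticulum stress lists rose. None of these lists was called by camera with an estimated correlation. All 33 tested mitosis genes fell, with a median log2 fold change of -2.13, and so did all 38 genes of DNA replication and S phase, with a median of -0.93. DLGAP5, a spindle protein, went from 35.02 ± 0.384 to 3.54 ± 0.675 RPKM (SD, n = 3 each) and RRM2, a subunit of ribonucleotide reductase, from 50.4 ± 1.03 to 10.5 ± 1.89 RPKM (SD, n = 3 each). Of 23 p53 targets 22 rose, and of 31 ATF4 and amino acid response genes 22 rose and none fell. Among 24 endoplasmic reticulum chaperones and degradation factors 17 rose and none fell. TP53INP1 went from 6.75 ± 2.42 to 37.2 ± 2.36 RPKM and DDIT3, the stress transcription factor CHOP, from 24.96 ± 5.82 to 88.4 ± 3.61 RPKM (SD, n = 3 each).

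In total 5592 of 12922 genes differed between 2-DG and NC by limma at an adjusted p under 0.05, 2916 higher and 2676 lower, and 1081 of these differed at least 2-fold, 420 higher and 661 lower. Median-of-ratios scaling gave 2761 higher and 2870 lower. With Nala replicates 2 and 3 kept apart the count was 6019. The 2 groups did not overlap at 52.1% of the tested genes, where chance gives 10%. Fold changes are on the log2(RPKM + 1) scale, which understates the change of low genes. No gene exceeded a mean of 1.21 reads per base, a narrow range that bears on the fold changes of abundant genes. Coordinates are those of GRCh38.p14.

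The 6 genes with the largest rise under the rule for named genes were KLHDC7B, LCN2, LAMP3, CLDN1, MIR3189 and CLGN. KLHDC7B (chromosome 22, 50545899 to 50551023) rose by 4.66 on the log2 scale (SE 0.163, limma adjusted p = 7.7e-07), from 1.97 ± 0.546 to 73.5 ± 7.03 RPKM (SD, n = 3 each). LCN2 (chromosome 9, 128149453 to 128153453), which encodes the secreted iron-siderophore binder lipocalin-2, rose by 4.48 (SE 0.277, limma adjusted p = 4.9e-06), from 4 to 11 reads in NC to 281 to 345 with 2-DG. LAMP3, a lysosomal membrane protein with 8 to 17 reads in NC, rose by 4.06 (SE 0.164), the tight junction protein CLDN1 by 3.86 (SE 0.187) and CLGN, a chaperone of the endoplasmic reticulum, by 3.72 (SE 0.196). MIR3189 (chromosome 19, 18386562 to 18386634) rose by 3.78 (SE 0.387, limma adjusted p = 8.7e-05), from 1 to 4 reads in NC to 28 to 48 with 2-DG. It lies inside GDF15, which lay at 58.4 to 62.8 RPKM in NC and 134.8 to 153.8 RPKM with 2-DG, so its reads cannot be told from those of the host gene.

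The 6 genes with the largest fall were PIF1, ALPI, PIMREG, CA9, TRAPPC3L and LMO1. PIF1 (chromosome 15, 64815632 to 64827062), a DNA helicase, fell by 3.59 on the log2 scale (SE 0.147, limma adjusted p = 8.7e-07), from 35.02 ± 4.57 to 1.99 ± 0.469 RPKM (SD, n = 3 each). PIMREG fell by 3.24 (SE 0.121) and the transcriptional cofactor LMO1 fell by 3.00 (SE 0.232), to 3 to 10 reads with 2-DG. The intestinal alkaline phosphatase ALPI fell by 3.51 (SE 0.573) and CA9, a hypoxia-induced carbonic anhydrase, fell by 3.07 (SE 0.527). Both were uneven among untreated cells, at 41.6 ± 35.3 and 28.2 ± 26.1 RPKM (SD, n = 3 each). TRAPPC3L fell by 3.05 (SE 0.506, limma adjusted p = 0.0013), to 0 to 2 reads with 2-DG. It overlaps CALHM5, as PIMREG overlaps PITPNM3, and strand use in the counting is not given in the sources used here.

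**Figure D2:**
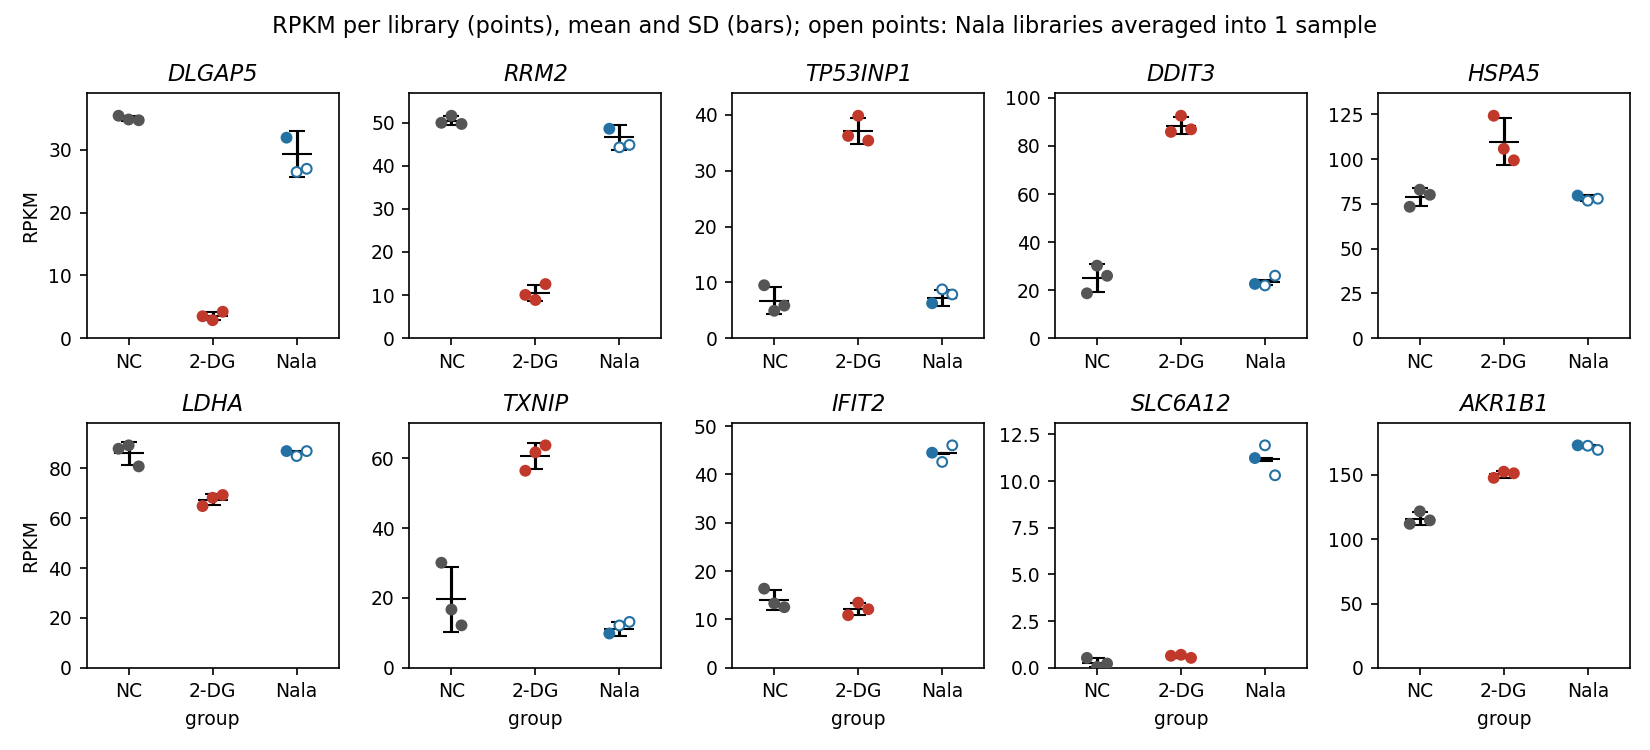
RPKM per library (points) for 10 genes in NC, 2-DG and Nala, with the mean and SD as bars (n = 3, 3 and 2) and the Nala libraries that were averaged into 1 sample as open points. DLGAP5 and RRM2 lie lowest with 2-DG, TP53INP1, DDIT3 and TXNIP highest with 2-DG, and IFIT2 and SLC6A12 highest with Nala.

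Mitosis and DNA replication were the gene lists with the smallest p in this comparison (camera adjusted p = 2.1e-29 and 1.9e-20). Neither was called with an estimated correlation (adjusted p = 0.195 with an estimated correlation for both). Adjusted over the list alone, the counts were again 33 and 38. KIF20A, a kinesin of cytokinesis, fell by 2.99 (SE 0.0971) and HMMR fell by 2.95 (SE 0.133). The replication factor MCM10 fell by 2.12 (SE 0.143) and the cell cycle transcription factor E2F2 fell by 2.11 (SE 0.185).

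The p53 targets had a median log2 fold change of 1.13 (camera adjusted p = 9.8e-13, adjusted p = 0.209 with an estimated correlation), and adjusted over the list alone 23 of 23 rose. TP53INP1 rose by 2.34 (SE 0.198), SESN2, a stress-induced regulator of growth signalling, by 1.81 (SE 0.126) and ZMAT3 by 1.80 (SE 0.183). The ATF4 and amino acid response genes had a median of 0.55 (camera adjusted p = 2.3e-10, adjusted p = 0.195 with an estimated correlation), and adjusted over the list alone 23 rose. The stress hormone FGF21 rose by 3.43 (SE 0.195), from 0 to 2 reads in NC to 71 to 111 with 2-DG, the glutathione-degrading enzyme CHAC1 by 2.84 (SE 0.385) and NUPR1 by 2.37 (SE 0.232). DDIT3 rose by 1.81 (SE 0.145) and overlaps MARS1.

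Of 24 endoplasmic reticulum chaperones and degradation factors 17 rose and none fell, or 18 adjusted over the list alone, with a median log2 fold change of 0.37 (camera adjusted p = 3.0e-07, adjusted p = 0.475 with an estimated correlation). The co-chaperone DNAJB9 rose by 1.78 (SE 0.144), HERPUD1 by 1.23 (SE 0.0729) and DNAJC3 by 1.18 (SE 0.112). HSPA5, the main chaperone of this compartment, rose by 0.47 (SE 0.0865, limma adjusted p = 0.0023). Of 34 N-glycosylation genes 13 rose and 3 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.0099, adjusted p = 0.507 with an estimated correlation). Its call was lost without 2-DG replicate 1 (camera adjusted p = 0.055).

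Of 21 genes of glycolysis and glucose uptake 15 fell and none rose, or 16 adjusted over the list alone, with a median log2 fold change of -0.25 (camera adjusted p = 2.0e-04, adjusted p = 0.454 with an estimated correlation). The aldolase ALDOC fell by 0.70 (SE 0.154), GPI, which interconverts glucose and fructose phosphates, fell by 0.55 (SE 0.0837) and PFKFB3 fell by 0.45 (SE 0.132). PFKFB3 was not called without NC replicate 2, NC replicate 3, 2-DG replicate 1 or 2-DG replicate 3 (limma adjusted p = 0.0756, 0.0803, 0.0507 and 0.0627). The lactate dehydrogenase subunit LDHA went from 86.0 ± 4.53 to 67.5 ± 2.32 RPKM (SD, n = 3 each, limma adjusted p = 0.0020) and fell by 0.34, while LDHB fell by 0.18 (limma adjusted p = 0.0236). LDHB was not called without NC replicate 2 or 2-DG replicate 3 (limma adjusted p = 0.0663 and 0.0825). Of 8 glucose-responsive MondoA and ChREBP targets 5 rose, with the same count adjusted over the list alone (camera adjusted p = 0.0129, adjusted p = 0.507 with an estimated correlation). TXNIP, a member of it that restrains glucose uptake, went from 19.7 ± 9.32 to 60.6 ± 3.76 RPKM (SD, n = 3 each) and rose by 1.67 (SE 0.258).

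BRD9, the bromodomain protein of the series title, was at 57.7 ± 6.28 RPKM in NC and 52.4 ± 4.98 with 2-DG (SD, n = 3 each, limma adjusted p = 0.278). EP300, an acetyltransferase, had a log2 fold change of 0.01 (SE 0.0846, limma adjusted p = 0.926) and MYC of -0.24 (SE 0.106, limma adjusted p = 0.101). The lactate transporters SLC16A1 and SLC16A3 had log2 fold changes of -0.14 and -0.16 (limma adjusted p = 0.215 and 0.158). SLC16A3 was called without 2-DG replicate 1 (log2 fold change -0.23, limma adjusted p = 0.0341).

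A further 7 lists were called by camera with 2-DG, none of them with an estimated correlation. Of 75 ribosomal protein genes 13 rose and 1 fell, or 5 and 1 adjusted over the list alone (camera adjusted p = 0.0073, adjusted p = 0.806 with an estimated correlation). Of 10 WNT targets 5 fell, or 8 adjusted over the list alone, AXIN2 among them at -1.47 with 2 to 4 reads per 2-DG library (camera adjusted p = 0.0073, adjusted p = 0.197 with an estimated correlation). Of 16 cytosolic heat shock genes 7 fell, with the same count adjusted over the list alone (camera adjusted p = 0.0247, adjusted p = 0.720 with an estimated correlation). Of 48 nuclear-encoded oxidative phosphorylation genes 7 fell and 1 rose, or 3 and 1 adjusted over the list alone (camera adjusted p = 0.0247, adjusted p = 0.806 with an estimated correlation). Of 20 mesenchymal and invasion genes 9 fell and 2 rose, or 10 and 2 adjusted over the list alone (camera adjusted p = 0.0281, adjusted p = 0.220 with an estimated correlation). FN1, which encodes fibronectin, was among those that fell at -1.18, and TWIST1 rose by 0.86. Of 21 apoptosis regulators 10 rose and 2 fell, or 12 and 2 adjusted over the list alone (camera adjusted p = 0.0323, adjusted p = 0.562 with an estimated correlation). BBC3, a pro-apoptotic p53 target, rose by 1.62. Of 14 NF-kB and inflammatory mediators 7 rose and 2 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.0456, adjusted p = 0.605 with an estimated correlation), and the chemokine CXCL2 rose by 2.58. The calls of 3 of these lists were lost on leaving out 1 library. That of heat shock went without NC replicate 2 (camera adjusted p = 0.116), that of NF-kB without 2-DG replicate 1 (camera adjusted p = 0.141), and that of oxidative phosphorylation without NC replicate 2 or 2-DG replicate 1 (camera adjusted p = 0.0673 and 0.163). The NF-kB list was also not called with the Nala pair kept apart (camera adjusted p = 0.0530), in the replicate block (camera adjusted p = 0.0647), with quantile normalization (camera adjusted p = 0.0543) or with values rescaled to a common library sum (camera adjusted p = 0.0506). Fry did not call ribosomal proteins, heat shock or oxidative phosphorylation (fry adjusted p = 0.136, 0.0578 and 0.233).

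The remaining lists were not called with 2-DG by camera, though fry called some of them. Those were SWI/SNF subunits, autophagy and lysosome, hexosamine metabolism, hepatocyte secreted proteins and interferon-stimulated genes (fry adjusted p = 0.0037, 0.0051, 0.0109, 0.0116 and 0.0240). For each remaining list the genes that rose and fell by limma are given first, and those adjusted over the list alone in brackets. Of 21 interferon-stimulated genes 3 rose and 9 fell (3 and 9 adjusted over the list alone), and of 25 SWI/SNF subunits 2 rose and 6 fell (0 and 6). SMARCA4, an ATPase of this remodeller, fell by 0.96. Of 20 hypoxia genes 3 rose and 7 fell (3 and 7), of 25 autophagy and lysosome genes 9 rose and 3 fell (9 and 3), and of 20 NRF2 and pentose phosphate genes 5 rose and 3 fell (4 and 3). The counts were 7 and 4 (7 and 4) of 19 for hexosamine, glycogen and mannose metabolism, 5 and 2 (3 and 0) of 24 for cholesterol synthesis, and 2 and 5 (2 and 6) of 13 for fatty acid synthesis. They were 4 and 2 (4 and 2) of 15 for fatty acid oxidation, 4 and 1 (4 and 1) of 9 for gluconeogenesis and the urea cycle, and 2 and 4 (2 and 4) of 12 for the hyperosmotic response. Lactate transport and pyruvate handling had 3 and 4 (3 and 4) of 19, among which MPC1, a subunit of the mitochondrial pyruvate carrier, rose by 1.43. Enzymes associated with lactylation had 6 and 4 (6 and 4) of 17, immediate early genes 5 and 2 (5 and 2) of 14, and ribosome biogenesis and MYC targets 1 and 7 (1 and 6) of 27. Replication-dependent histones had 5 and 3 (5 and 4) of 18. Of the liver lists, acute phase and complement had 1 and 3 (1 and 3) of 6, hepatocyte secreted proteins 0 and 2 (0 and 2) of 5, and liver regulators 1 and 1 (1 and 1) of 6. The acute phase list had a median of -0.48 and a mean of 0.01, because LCN2 belongs to it. Median and mean also differed in sign for hypoxia (0.00 and -0.16) and histones (0.13 and -0.04). Markers of other cell types were mostly under the filter, with 1 endothelial (0 and 0), 3 fibroblast (0 and 2) and 4 immune (0 and 2) genes tested. None of the 13 listed mitochondrially encoded mRNAs was found in the table, so none was tested.

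**Figure D3:**
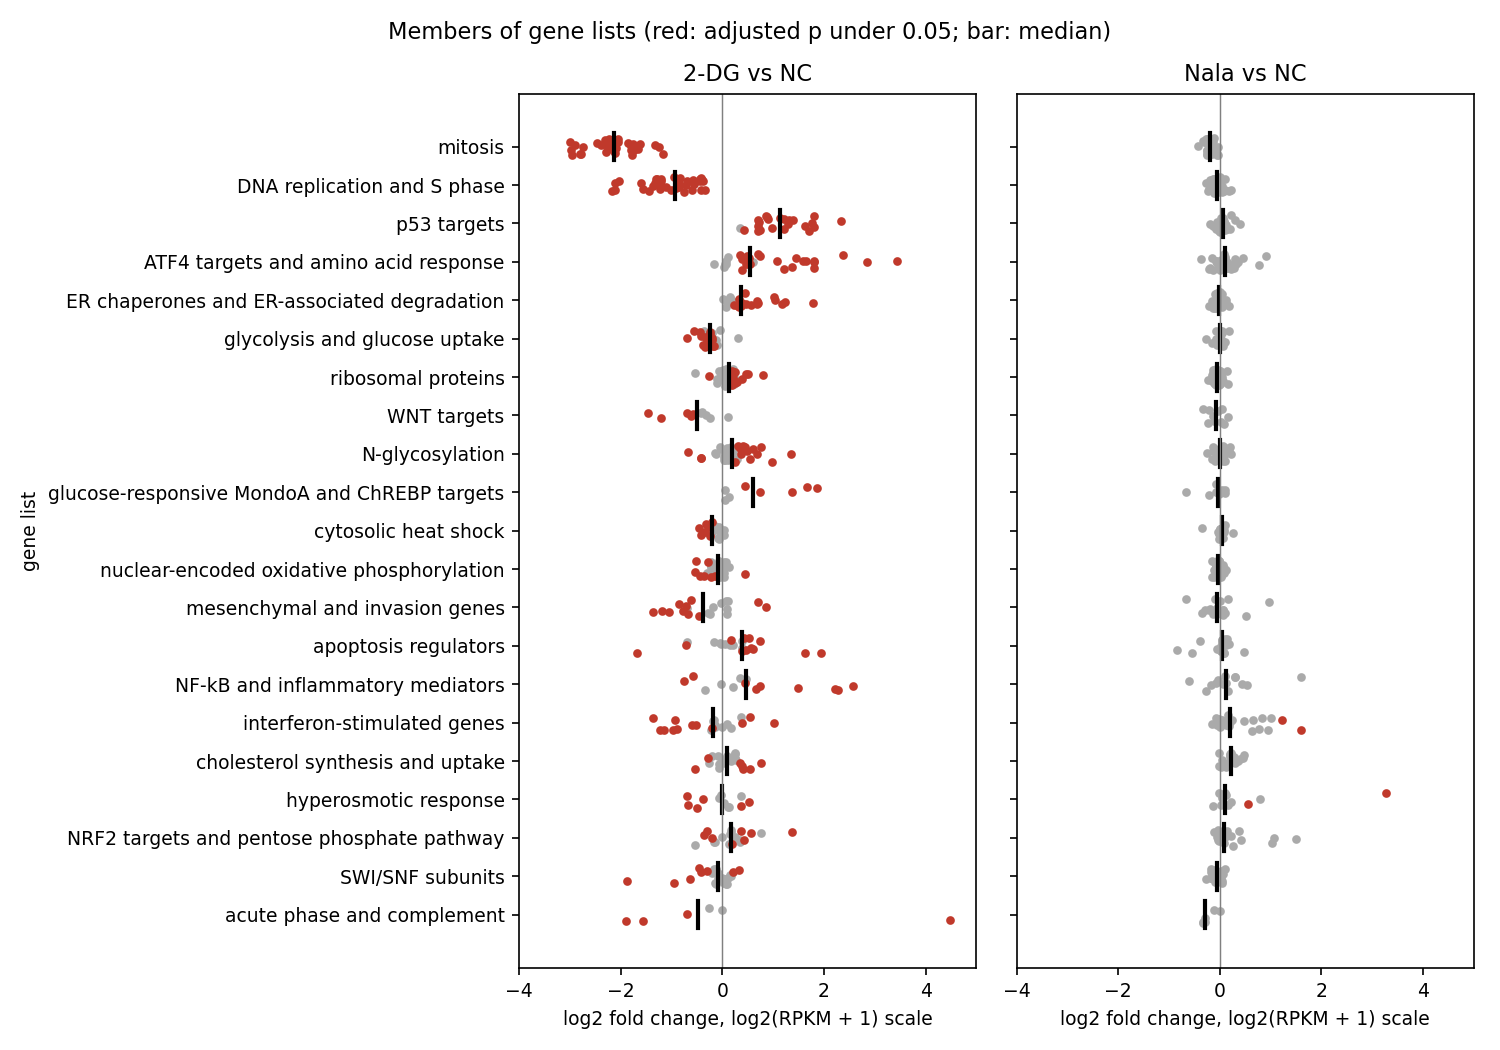
Log2 fold changes on the log2(RPKM + 1) scale of the tested members (points) of the lists called by camera for 2-DG or for Nala against NC, with genes past a limma adjusted p of 0.05 in red and the list median as a bar. Mitosis has its median at -2.13 with 2-DG and -0.20 with Nala.

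With Nala 8 genes rose, among them 2 of 12 hyperosmotic response genes and 2 of 21 interferon-stimulated genes. Both lists were called by camera at the preset correlation, neither with an estimated correlation (adjusted p = 0.163 and 0.351 with an estimated correlation) and the hyperosmotic list alone by fry (fry adjusted p = 0.0071, against 0.0771 for interferon). SLC6A12, a betaine transporter induced by osmotic stress, went from 0.268 ± 0.246 (SD, n = 3) to 11.2 ± 0.0851 RPKM (SD, n = 2), a log2 fold change of 3.28. It had 1 to 12 reads in NC and 240 to 277 with Nala, and its Nala libraries spread more than this SD, from 10.3 to 11.9 RPKM. IFIT2, an interferon-induced protein, went from 14.1 ± 2.03 (SD, n = 3) to 44.4 ± 0.136 RPKM (SD, n = 2), with Nala libraries from 42.6 to 46.0 RPKM. IFIT2 rose by 1.60 and IFIT3 by 1.22. EREG, which encodes the growth factor epiregulin, rose by 0.87, and AKR1B1, the aldose reductase that makes the osmolyte sorbitol, by 0.56.

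Of the 12922 genes, 8 rose and 0 fell with Nala by limma, while 725 had an unadjusted p under 0.05 and voom on the recovered reads called 64 higher and 8 lower. The groups did not overlap at 23.0% of genes, where chance gives 20% for 3 against 2. Kept apart, Nala replicates 2 and 3 gave 64 genes, 59 higher and 5 lower, and all 8 genes were among them. The count was 19 without NC replicate 1, 4 without NC replicate 3, 2 without Nala replicate 1 and 20 without Nala replicate 3.

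SLC6A12 (chromosome 12, 183848 to 214157) had an SE of 0.200 and a limma adjusted p = 2.0e-04. IFIT2 (chromosome 10, 89302046 to 89309271) had an SE of 0.133 and a limma adjusted p = 0.0023. IFIT3 (chromosome 10, 89327997 to 89340968) and EREG (chromosome 4, 74365145 to 74388749) each had a limma adjusted p = 0.0197, with SEs of 0.147 and 0.105. AKR1B1 (chromosome 7, 134442350 to 134459239) went from 116.1 ± 5.03 (SD, n = 3) to 172.0 ± 1.37 RPKM (SD, n = 2), with a limma adjusted p = 0.0055. IFIT2 and IFIT3 overlap the LIPA gene. THPO, which encodes thrombopoietin, rose by 1.70 (SE 0.164, limma adjusted p = 0.0055). PPIAP46 (chromosome 15, 74361552 to 74362041), which was named after its values were seen, rose by 2.54 (SE 0.133, limma adjusted p = 1.0e-04). It is a transcribed pseudogene of the PPIA family inside CYP11A1, so the origin of its reads is uncertain.

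Without Nala replicate 1, which leaves a lone Nala sample assumed to vary like the other groups, IFIT2, IFIT3, EREG, AKR1B1 and THPO were not called (limma adjusted p = 0.0965, 0.289, 0.304, 0.216 and 0.145). IFIT3 and EREG were also not called without NC replicate 2 (limma adjusted p = 0.0635 and 0.0771). Without NC replicate 3 this held for IFIT3, EREG and AKR1B1 (limma adjusted p = 0.0928, 0.099 and 0.0536). Their log2 fold changes stayed between 0.56 and 1.79.

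Of 21 interferon-stimulated genes 2 rose with Nala and none fell, or 9 and none adjusted over the list alone (camera adjusted p = 1.0e-10, adjusted p = 0.351 with an estimated correlation). Of 12 hyperosmotic response genes 2 rose, or 3 adjusted over the list alone (camera adjusted p = 4.1e-05, adjusted p = 0.163 with an estimated correlation), and it was the 1 list of 8 kept by fry. Its median log2 fold change was 0.11 and its mean 0.43, which SLC6A12 raises. The inositol transporter gene SLC5A3, which overlaps MRPS6, lay at 10.4 to 13.8 RPKM in NC and 18.7 to 24.4 RPKM with Nala and was not called. All 33 mitosis genes lay below NC with a median of -0.20, but none was called, over all genes or adjusted over the list alone (camera adjusted p = 1.7e-11, adjusted p = 0.656 with an estimated correlation). Cholesterol synthesis and uptake had a median of 0.21 with 0 of 24 called, and 0 adjusted over the list alone (camera adjusted p = 5.9e-08, adjusted p = 0.739 with an estimated correlation).

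A further 4 lists were called by camera with Nala, without a gene past the limma threshold. These were ribosomal proteins (median -0.06, camera adjusted p = 6.1e-05, adjusted p = 0.838 with an estimated correlation), NRF2 and pentose phosphate genes (median 0.08, camera adjusted p = 0.0095, adjusted p = 0.838 with an estimated correlation), SWI/SNF subunits (median -0.05, camera adjusted p = 0.0246, adjusted p = 0.656 with an estimated correlation) and acute phase and complement (median -0.29, camera adjusted p = 0.0496, adjusted p = 0.838 with an estimated correlation). Adjusted over the list alone, 3 NRF2 genes and 0 of each of the other lists rose. The NRF2 call was lost without NC replicate 1 (median 0.0032, camera adjusted p = 0.494), and that of ribosomal proteins without NC replicate 2 or Nala replicate 1 (medians -0.024 and -0.0087, camera adjusted p = 0.235 and 0.213). SWI/SNF was not called without NC replicate 2, Nala replicate 1 or Nala replicate 2 (medians -0.036, -0.058 and -0.050, camera adjusted p = 0.221, 0.118 and 0.0507). Acute phase was not called without NC replicate 1, NC replicate 3 or Nala replicate 3 (medians -0.16, -0.23 and -0.28, camera adjusted p = 0.494, 0.0612 and 0.0624), nor with median-of-ratios scaling, quantile normalization or values rescaled to a common library sum (camera adjusted p = 0.0668, 0.0658 and 0.0521).

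The genes followed in every comparison were not called with Nala. BRD9 was at 53.9 ± 1.80 RPKM (SD, n = 2), with a log2 fold change of -0.09, and EP300 had one of 0.09. LDHA and LDHB had log2 fold changes of 0.01 and 0.00, SLC16A1 of -0.12, SLC16A3 of -0.03, HSPA5 of 0.00, DDIT3 of -0.07, MYC of -0.05 and TXNIP of -0.67, with limma adjusted p between 0.862 and 0.997.

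Nala and 2-DG differed at 4639 genes by limma, 2310 higher and 2329 lower with Nala, and at 5858 with Nala replicates 2 and 3 kept apart. Titles gave 48 h for both, while the series design gave 24 h for Nala and 48 h for 2-DG, so time may differ between them. Mitosis genes were again on one side, with 33 of 33 higher with Nala than with 2-DG (median 1.97, camera adjusted p = 1.0e-29, adjusted p = 0.204 with an estimated correlation). DLGAP5 was higher by 2.75 (SE 0.140) and RRM2 by 2.06 (SE 0.129). Of the p53 targets 22 of 23 were lower with Nala (median -0.92, camera adjusted p = 3.5e-13, adjusted p = 0.208 with an estimated correlation). Among interferon-stimulated genes 11 of 21 were higher with Nala and 1 was lower (camera adjusted p = 7.0e-05, adjusted p = 0.349 with an estimated correlation). Adjusted over the list alone these counts were 33, 23, and 12 against 1.

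LDHA was higher with Nala than with 2-DG by 0.35 (SE 0.0688, limma adjusted p = 0.0040), and TXNIP had a log2 fold change of -2.34 (SE 0.289, limma adjusted p = 3.7e-04). BRD9 did not pass the test (log2 fold change 0.05, limma adjusted p = 0.771). In all 14 lists were called by camera in this comparison and none with an estimated correlation, where the adjusted p ranged from 0.204 to 0.704. Without Nala replicate 1 the count of genes was 2212. The call of the mesenchymal list was lost without 2-DG replicate 2, 2-DG replicate 3 or Nala replicate 1 (camera adjusted p = 0.0504, 0.0586 and 0.0526), and with median-of-ratios scaling (camera adjusted p = 0.0535). Fry did not call ribosomal proteins or heat shock here (fry adjusted p = 0.0592 and 0.0573).

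In all 3 genes rose with both treatments, EREG and AKR1B1 among them. This compares with 1.81 for independent lists of these sizes. The 50 simulations of unchanged groups sharing the NC libraries gave 0.04 on average. They hold no changed genes, so an overlap near 0 was set in advance and is not the chance level for these lists. The count depended on the libraries and the test, at 0 to 13 on leaving out 1 library, 29 with Nala replicates 2 and 3 kept apart and 30 by voom. THPO was the 1 gene changed in opposite directions, at 1.30 ± 0.101 RPKM in NC, 0.404 ± 0.0401 with 2-DG (SD, n = 3 each) and 6.48 ± 0.677 with Nala (SD, n = 2), or 14 to 16, 4 to 5 and 70 to 95 reads. The 1 gene compares with 1.66 for independent lists of these sizes, and with 0 in the simulations, which have the same limit. The count was 0 to 5 on leaving out 1 library, 9 with the pair kept apart and 11 by voom. Of the 8 genes that rose with Nala, 6 also differed between Nala and 2-DG, SLC6A12 by 2.91 (limma adjusted p = 1.7e-05) and IFIT2 by 1.79 (limma adjusted p = 2.6e-05).

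Across genes, which are not independent replicates, the log2 fold changes of the 2 treatments had a Pearson correlation of 0.232. The value simulated for unchanged groups with shared NC libraries was 0.444. The simulation holds no changed genes, while 5592 genes changed with 2-DG, which widens the spread of fold changes and can lower a correlation. The 2 correlations therefore do not show whether the responses were more or less alike than chance. The covariance was 0.0314 against 0.0141 simulated, a difference of 0.0173. NC could not be split with 2 libraries in each part, so part of the excess may come from the shared controls.

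**Figure D4:**
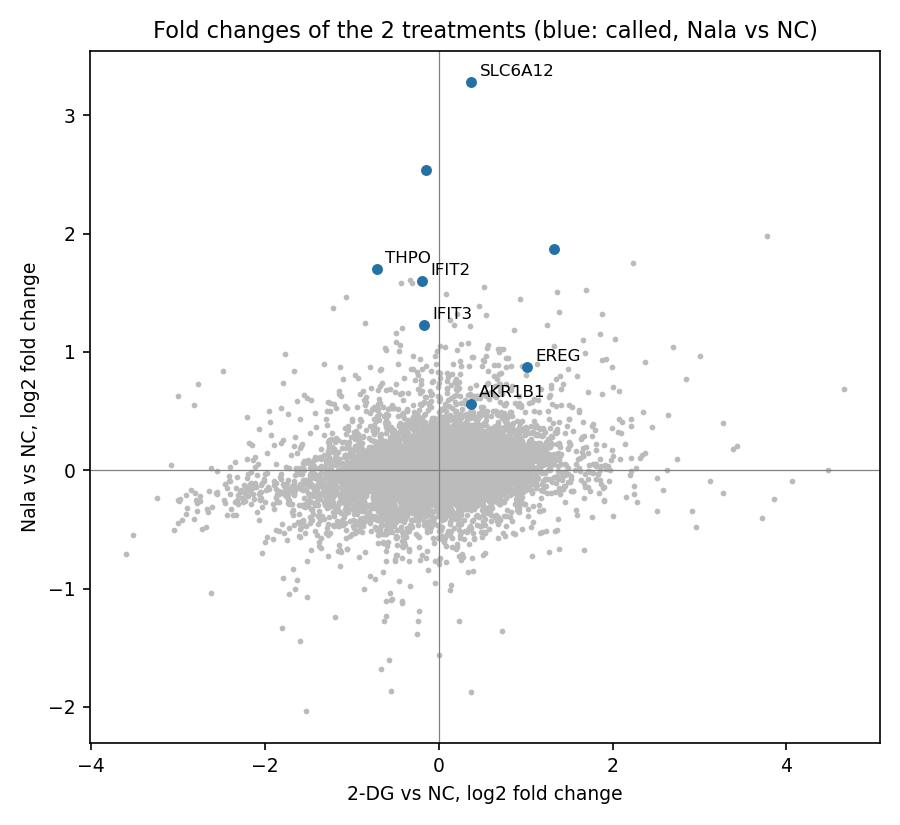
Log2 fold change with Nala (y axis) against that with 2-DG (x axis), both relative to NC on the log2(RPKM + 1) scale, for 12922 genes, with the 8 genes called for Nala in blue and those named by the rule labelled. SLC6A12 lies highest at 3.28, and THPO lies to the left of 0 at -0.71.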

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

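The alternatives were fixed before the data were examined, except the block with Nala replicates 2 and 3 kept apart and voom on the recovered reads. Those 2 were chosen after seeing the data. The fit with Nala replicates 2 and 3 kept apart was the main fit of the design fixed beforehand, and became an alternative when the pair was averaged. Apart from a minimum fold of 2 (1081 genes), the count for 2-DG against NC stayed within 1.5 times of 5592 under each alternative run, 4270 to 6091 on leaving out 1 library. For Nala against 2-DG a minimum fold of 2 gave 1037 genes, and leaving out 1 library gave 2212 (without Nala replicate 1) to 5261. The Nala against NC count was 25 without a filter, 15 with at least 5 RPKM, 16 with values rescaled to a common library sum, 13 with median-of-ratios scaling, 17 with quantile normalization, 64 with the pair kept apart, 72 by voom, and 2 to 20 on leaving out 1 library (19 without NC replicate 1, 4 without NC replicate 3, 2 without Nala replicate 1, 20 without Nala replicate 3). The 8 genes were among the calls in these settings except without NC replicate 2 (6 of them), NC replicate 3 (4) and Nala replicate 1 (2), and 6 were without the trend and in the fit of the compared groups alone. In the same order genes changed in the same direction by both treatments numbered 5, 6, 6, 5, 8, 29 and 30 in place of 3, and 0 to 13 on leaving out 1 library (8, 0, 0 and 8 in the same order, and 13 without 2-DG replicate 1). Genes changed in opposite directions numbered 2 without a filter, with 5 RPKM, rescaled or quantile normalized, 9 with the pair apart and 11 by voom in place of 1, and 0 to 5 on leaving out 1 library (5 without NC replicate 1, 3 without 2-DG replicate 1, 0 without Nala replicate 1, 2 without Nala replicate 3). The correlation of fold changes was 0.221 to 0.299 on leaving out 1 library, and 0.275, 0.299 and 0.263 without NC replicate 1, 2 and 3. The cause of these shifts was not tested.

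Replicate numbers did not pair the libraries, as deviations of libraries with the same number correlated at -0.119 to 0.0772. The replicate block, with Nala replicates 2 and 3 kept apart, gave 5867 genes for 2-DG against NC, 31 for Nala against NC, 5708 for Nala against 2-DG, 14 in the same and 5 in opposite directions, and a correlation of 0.239.

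Of 855 alternatives for named genes 821 left direction and call as they were, 18 lost the call, 1 gained it, and 15 turned the sign of a gene that was not called. EP300 with 2-DG went to -0.014 with median-of-ratios scaling and ranged from -0.052 (without NC replicate 1) to 0.066 on leaving out 1 library. With Nala, LDHA went to -0.0011 with median-of-ratios scaling and ranged from -0.035 (without NC replicate 3) to 0.036, and LDHB went to -0.0055 and ranged from -0.020 (without NC replicate 3) to 0.035. HSPA5 went to 0.0014 rescaled and 0.025 quantile normalized and ranged from -0.053 to 0.034 (without NC replicate 2). DDIT3 ranged from -0.257 to 0.075 and MYC from -0.115 to 0.030, each turned by leaving out NC replicate 2. LDHB with 2-DG lost its call without a filter and by voom. Of 481 alternatives for list tests 407 kept the call and 74 lost it, 37 of these with an estimated correlation, 12 with fry and 17 on leaving out 1 library. The other 8 were NF-kB with 2-DG (rescaled, quantile normalized, the pair apart and the block), acute phase with Nala (rescaled, median-of-ratios and quantile normalized) and the mesenchymal list for Nala against 2-DG (median-of-ratios). For the counts of list members that rose or fell, 365 of 407 alternatives were classed as the same, 25 as weaker and 17 as stronger. The count tests planned for the case of a table of counts were not run, and voom on the recovered reads is the alternative that uses reads. In the simulated data most genes changed by the smallest fold were not recovered. Few genes were changed there, and depth was not varied. The simulation therefore sets no detection limit for 2-DG, where many genes changed and some smaller changes, as of PKM and GAPDH, were called.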

Other observations

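All tests of explanations below were chosen after the results were seen. Some members of lists that were not called with 2-DG were picked after their values were seen. SMARCA4 went from 53.8 to 64.1 RPKM in the NC libraries to 27.1 to 32.7 RPKM with 2-DG. DPF1, another SWI/SNF subunit, lay at 5.46 to 7.26 RPKM in NC and 0.714 to 1.119 RPKM with 2-DG (11 to 17 reads). MPC1 lay at 7.98 to 9.01 RPKM in NC and 21.97 to 27.6 RPKM with 2-DG. ACSS2, an acetyl-CoA synthetase linked to lactylation, lay at 31.2 to 35.1 RPKM in NC, 46.8 to 54.8 with 2-DG and 51.3 to 58.2 with Nala, where it was not called.

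The 6 libraries of 2-DG and NC can be split 10 ways, too few for a share under 0.05. The real grouping gave 5592 genes, 1 split in all gave as many, and the highest of the other splits gave 1.

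Several liver transcripts, though not VTN or CEBPA, were near 0 in libraries given as HepG2, and 22 of 36 held genes were under 1 RPKM in every group. SMARCB1 lay between 0 and 1.59 RPKM, KRT7 between 110.0 and 140.3 and L1CAM between 117.2 and 143.1. ALDOA (3.31 to 5.23 RPKM) and ACACA (0.143 to 0.635), which most cells use, were low as well. Neither a loss of reads on their assignment to genes nor a wrong cell line label or a changed subline was tested, and with the former a value near 0 does not show that a gene is silent. The cause is left open, since low values of these genes are themselves the pattern, no reference profile of the line was analysed here and only 14 of 29 listed secreted proteins were in the table. The table holds 0 genes that are at 0 in every library, so the missing proteins may have had no reads, which was not tested.

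The range of RPKM was narrow, with a highest value of 229.6. Abundant genes left out after RPKM was computed are argued against, because recovered reads made up 99.9% of each counted total. Genes left out before the total was counted would not show in that share, and this was not tested. None of the 13 listed mitochondrially encoded mRNAs was found in the table. A transformation is argued against by whole reads at 100% of genes. Removal of repeated reads is a candidate explanation, since the 2 alike Nala libraries spread less than counting noise among the densest genes (0.746, against 1.05 among the sparsest). It would hold down the differences between abundant genes and, for these, the chi-square on which the averaging of that pair rests.

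Of the 8 genes that rose with Nala, 2 are among 12 hyperosmotic and 2 among 21 interferon-stimulated genes, and neither list was called with an estimated correlation (adjusted p = 0.163 and 0.351). Each of the 8 genes kept at least 95.1% of its log2 fold change on leaving out 1 NC library (68.4% less 2 SE), so these fold changes did not rest on 1 NC library. A call already needs NC values that lie close together. The outcome was therefore largely set by the choice of genes and is no separate evidence on an outlying NC library. The calls were less stable, and 8, 6 and 4 of the 8 genes remained called without NC replicate 1, 2 and 3. IFIT3 went from 1.22 (SE 0.147) to 1.27 (SE 0.165) and 1.21 (SE 0.172) without NC replicate 2 and 3, EREG from 0.87 (SE 0.105) to 0.83 (SE 0.114) and 0.84 (SE 0.122), and AKR1B1 from 0.56 (SE 0.0551) to 0.56 (SE 0.0659) without NC replicate 3, so that these calls ended with a larger SE and fewer libraries. Time in culture stays open. By the titles, with 24 h for NC and 48 h for Nala, it cannot be told apart from treatment. Of the 8 genes 6 also differed between Nala and 2-DG, for which titles give the same 48 h. By the series design, with 24 h for Nala, its time would match the NC titles and differ from that of 2-DG. Osmolarity of the added 40 mM solute is left open too, since the rise of the hyperosmotic genes that raises it cannot also test it and no salt control was analysed here. With 40 mM 2-DG, which also has effects of its own, 2 of these 12 genes rose and 4 fell, and SLC6A12 was at 0.625 RPKM (limma adjusted p = 0.119 against NC), compared with 11.2 RPKM with Nala. AKR1B1 rose with both, at 116.1 RPKM in NC, 150.5 with 2-DG (limma adjusted p = 3.8e-04) and 172.0 with Nala. A biological effect of Nala was not tested apart from these.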
